A study of Caenorhabditis elegans with 57 samples.

How the data were processed

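RNA and chromatin were measured in *C. elegans* fathers, offspring and grandoffspring that, per the labels, differed in whether the sperm genome had carried H3K27me3, the histone mark placed by the PRC2 complex of MES-2, MES-3 and MES-6. Per the labels, mothers came from the Hawaiian strain CB4856 and fathers from the Bristol strain N2, so that reads over sequence differences could be assigned to the oocyte or the sperm genome. The labels also name a *fem-2* strain and a temperature at which females were raised. These temperatures and that of collection were the same for all samples. Offspring of fathers homozygous for a *mes-3* mutation are called M+P- here, and those of heterozygous fathers M+P+. The first cross used the allele bn35 and gave hermaphrodite germlines (2 libraries per group), male germlines (4 per group) and newly hatched L1 larvae (3 per group). The second cross used the allele bn199 and gave F1 hermaphrodite germlines (3 per group) and germlines of F2 descendants of M+P- worms, labelled GM+GP- (3 libraries). Male germlines of *mes-3* mutants (M+Z-, from heterozygous mothers) and of *him-8* males, which stand for wild-type fathers, had 3 libraries each. Per the labels the *mes-3* mutant males were *him-8* too, so both groups of fathers shared *him-8*. Per the labels' protocols, germline samples held the part of the gonad distal to the bend from day 1 adults, and RNA was selected for poly(A) tails. CUT&RUN, in which a nuclease releases the DNA bound by an antibody, was done for H3K27me3 and H3K36me3 in hermaphrodite germlines of both crosses and in *him-8* males, with 2 libraries per group and mark. That made 33 RNA, 12 H3K27me3 and 12 H3K36me3 libraries.

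The authors deposited raw counts per gene. Per the design text in the labels, RNA reads were mapped to the ce10 genome paired-end for differential expression and single-end for the allele assignment. Tools listed per the submitters' processing notes were TopHat2 2.1.1, Bowtie2 2.3.5.1, HTSeq, DESeq2 1.22.2 and DESeq, with no role given for each. Whether CUT&RUN reads were counted over gene bodies or exons is not given in the sources used here, nor is the use of strand in counting, so overlapping and antisense genes and near-identical family members (F-box, *clec*, *msp* and histone genes) have uncertain counts. The counts of reads on the oocyte and the sperm allele are the authors', per the file headers, and cover only genes with a usable sequence difference. The score values per gene of each CUT&RUN library are, as deposited by the authors, z-scores per the file headers, and lie near a mean of 0 over genes. Their formula is not given in the sources used here. These scores were used only as levels beside the counts. The log2 fold changes and adjusted p-values of the authors' deposited table were set beside the calls made here. That table names 1 group per comparison and not the other group. Single-end RNA counts, and the group values of normalised expression in that table, were not used. The number of columns of per-sample values left unused for want of a matching label was 0.

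Gene names and chromosomes came from a RefSeq gene table of assembly WBcel235, matched on the sequence name. It matched 44080 of 45461 genes of the RNA table, 44256 of 45624 of the CUT&RUN table and 19762 of 20258 genes of the authors' table. Because the assembly differs from ce10, no coordinates are printed. Repeated gene names were dropped (3 in the z-score table and 3 in the authors' table). No pair of libraries in a group was identical among 47 pairs, and the chi-square per gene between them ran from 4.64 to 350, so each library counted as 1 replicate. The labels call the germline samples biological replicates and do not give their parents or days of collection. The p-values therefore measure the spread between these samples.

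Total counts per RNA library ran from 5706650 to 19191934, with 9210 to 18087 genes detected and 1.15% to 6.66% of counts on ribosomal RNA genes. Reads assigned to an allele numbered 174826 to 431318 in 26 RNA libraries. H3K27me3 libraries held 2797547 to 25714782 counts and H3K36me3 libraries 1701400 to 41980395. Allele-assigned reads numbered 803306 to 1821852 for H3K27me3 and 577465 to 2084823 for H3K36me3, in 10 libraries each. A gene with no counts in a library lies below a floor of 3 counts, which covers counting error only.

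Differences between groups were tested with edgeR 4.0.16 (quasi-likelihood F-test on the raw counts, TMM scaling, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. Standard errors (SE) are those of the log2 fold change, taken from its F statistic. Only the groups compared entered each fit. The difference of the M+P- effect between tissues was tested as an interaction in a fit of all first-cross RNA libraries. For allele counts, the test was of the interaction of allele and history with the library as a block, for genes with a mean of at least 10 allele reads per library. A paternal share is the percent of allele-assigned reads on the sperm genome, compared between groups by an exact two-sided permutation test. The smallest p this can give is 0.333 for 2 against 2 libraries, 0.1 for 3 against 3 and 0.0286 for 4 against 4. Levels are counts scaled by library size and TMM factor (CPM), given with the SD, and log2 CPM used a prior count of 2. Gene lists were tested against the other genes with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. DESeq2 1.42.0 was run as an alternative. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

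The groups, tests, alternatives, 17 gene lists and the rule for named genes were fixed before the data were examined. Alternatives that single out F1 M+P- replicate 3 or male M+P+ replicate 3, and the estimated correlation for chromatin at the higher genes, were chosen after seeing the data. The 17 lists covered PRC2 and MES-4, H3K27 demethylases, neuronal genes, neuropeptides, homeodomain factors, muscle, intestine, pharynx, cuticle and hypodermis, somatic gonad, spermatogenesis, oogenesis, germline core and meiosis, heat shock, mitochondrially encoded genes, replication-dependent histones, and synMuv and dREAM genes. The mitochondrial list had 0 members in the table. X-linked and autosomal genes were tested beside them. Genes shared by lists were *ceh-18* and *lim-7* (homeodomain and somatic gonad), *tnt-2* (muscle and somatic gonad) and *elt-1* (cuticle and spermatogenesis). The rule named, per RNA comparison, the 8 largest rises and the 8 largest falls among called genes with a mean CPM of at least 1, no overlap between the libraries of the groups and a letters-and-number name. It added up to 3 called members per list with the smallest adjusted p, and always *mes-3*, *mes-2*, *mes-6*, *mes-4*, *him-8*, *fem-2* and *glh-1*. A gene named outside the rule is said to be so. Alternatives were RLE scaling, no filter on low counts, a mean CPM of at least 1, DESeq2, the replicate number as a block, all germline libraries of a cross fitted together, allele minima of 30 and 5 reads, and leaving out each library.

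Replicate numbers are shared by the groups in the labels. Deviations of same-numbered libraries from their group means correlated at 0.175 to 0.442 in the comparison of F2 with F1 M+P+ germlines, over 0.1 for each of the 3 pairs, which by the rule fixed beforehand pairs those samples. With the replicate block, that comparison called 634 genes, 393 higher and 241 lower, and without it 266. The pairing comes from this hint in the data and not from the labels. In the other comparisons the numbers did not meet the rule, which needs at least 3 pairs, each over 0.1. Those with 2 libraries per group have 2 pairs and could not meet it.

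Each test was checked on simulated data drawn from the real means, depths and spreads, with 100 genes changed 2-fold and 100 changed 4-fold. It found 65 and 86 of them in fathers (8604 genes), 67 and 90 in first-cross hermaphrodite germlines (8236 genes), 51 and 64 in male germlines (8936 genes), 26 and 62 in larvae (13785 genes) and 76 and 96 in F2 germlines (8105 genes). In F1 germlines it found 0 and 0 with all 6 libraries (7700 genes), and 78 and 96 without M+P- replicate 3 (8133 genes). For F2 against F1 M+P- germlines it found 0 and 0 (7936 genes). For H3K27me3 it found 11 and 84 in the first cross, 57 and 81 in F1 and 68 and 87 in F2. For H3K36me3 the values were 0 and 0, 35 and 75, and 11 and 74. Allele tests found 32 and 61 in hermaphrodite germlines, 39 and 83 in male germlines, 0 and 9 in larvae and 30 and 76 in F1. The tissue interaction found 5 and 61 (17100 genes). Unchanged genes were called too: 3 in fathers, 12 in hermaphrodite germlines, 3 in male germlines, 8 in larvae and 12 in F2. In F1 they numbered 2 with all 6 libraries and 13 without M+P- replicate 3. In the first cross, F1 and F2 they numbered 3, 4 and 14 for H3K27me3 and 0, 10 and 4 for H3K36me3. Allele tests called 1 in hermaphrodite germlines, 6 in male germlines, 0 in larvae and 1 in F1, and the tissue interaction 3.

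F2 GM+GP+ germlines are named in the design text and were not analysed here. F2 libraries were therefore set against F1 M+P+ germlines, so that generation and history cannot be told apart in that comparison. F1 M+P- replicate 3 had no allele columns, so allele results for F1 rest on 2 M+P- libraries.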

Results

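The data comprised 33 RNA libraries and 24 CUT&RUN libraries from *C. elegans*: *mes-3* mutant and *him-8* fathers, offspring that per the labels inherited a sperm genome with (M+P+) or without (M+P-) H3K27me3, and F2 descendants. RNA libraries held 5706650 to 19191934 counts each. Comparisons asked which genes changed in the mutant fathers, in the germlines and larvae of their offspring and in the next generation, on which parental allele, and with what H3K27me3 and H3K36me3 levels. Groups held 2 to 4 libraries, and each value carries its own n or that of its comparison.

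In germlines of *mes-3* mutant fathers, genes of neurons, muscle and cuticle were among those that rose against *him-8* males (n = 3 per group). Fathers had no allele reads, so RNA of somatic tissue carried along in dissection cannot be told apart from RNA of germ cells. Genes with reads numbered 13235 to 15111 in mutant and 10996 to 13277 in *him-8* libraries. *unc-31*, which is needed for release from dense-core vesicles, averaged 16.42 ± 4.62 CPM against 1.504 ± 0.662 (log2 fold change 3.42 ± 0.41 SE, adjusted p = 0.00313). The neuropeptide gene *nlp-9* averaged 17.1 ± 1.33 CPM against 2.00 ± 0.229 (3.08 ± 0.25, adjusted p = 0.000518), and *ttn-1*, which encodes a titin of muscle, rose by 1.55 ± 0.20 (adjusted p = 0.00448). Among the named genes with counts in *him-8* libraries, the largest fitted rise was that of *pes-7* (34.9 CPM against 0.105, log2 fold change 8.24 ± 0.63). The acyltransferase gene *oac-36* came next (27.9 against 0.0902, 7.92 ± 0.60), both at adjusted p = 0.000417. Of the genes without counts in all *him-8* libraries, *pes-10* averaged 5.79 ± 1.2 CPM in mutant fathers, the nuclear receptor gene *nhr-81* 5.35 ± 1.70, the folate transporter gene *folt-1* 5.06 ± 1.77, the collagen gene *col-109* 4.90 ± 1.16 and the lectin genes *clec-163* and *clec-198* 3.44 ± 0.622 and 3.3 ± 0.251.

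*mes-3* RNA itself averaged 31.9 ± 10.3 CPM in mutant and 42.7 ± 2.20 in *him-8* fathers (log2 fold change -0.42 ± 0.23, adjusted p = 0.332). Its level gives no firm check of the labels. The other always-named genes were not called: *mes-2* 0.02, *mes-6* 0.09, *mes-4* -0.10, *him-8* -0.23, *fem-2* -0.19 and *glh-1* -0.04 on the log2 scale. In all, 622 genes rose and 117 fell of 8873 tested (edgeR). DESeq2 called 1089. The largest falls were *tcl-2* (-2.25 ± 0.44), *wdfy-3* (-1.39), the F-box genes *fbxa-191* (-1.37) and *fbxa-192* (-1.16), *pign-1* (-1.07), *arrd-13* (-0.90), *fem-3*, which directs germ cells to become sperm (-0.83 ± 0.19), and *sql-1* (-0.79).

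Of 14 neuronal genes tested in fathers, 3 rose and 11 were not called (6 adjusted over the list alone). They were *unc-31*, *ida-1* (4.67) and the proprotein convertase gene *egl-3* (4.03). The list stood above other genes (median log2 fold change 1.07, adjusted p = 0.0238), and adjusted p = 0.649 with an estimated correlation. Of 20 muscle genes, 4 rose, among them *unc-89* (2.16), the ryanodine receptor gene *unc-68* (1.64) and *ttn-1* (4 higher and 1 lower adjusted over the list alone), with a median of 1.39 (adjusted p = 0.0238, and adjusted p = 0.874 with an estimated correlation). Of 48 cuticle genes 7 rose (8 adjusted over the list alone), including *col-109*, *col-60* (2.72) and *col-38* (1.78). The list test gave adjusted p = 0.133. Called members of other lists were *nlp-9* and the insulin-like *ins-7* (2.47) of 9 neuropeptide genes, *ceh-20* (3.68), *lim-7* (3.46) and *ceh-43* (1.85) of 11 homeodomain genes, and *gon-1* (4.06) and *lim-7* of 10 somatic gonad genes (2, 3 and 3 adjusted over the list alone). Their list tests gave adjusted p = 0.0708, 0.312 and 0.189. Intestinal genes had a median of 1.13 with 0 of 11 called (0 adjusted over the list alone, adjusted p = 0.459).

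Among 76 spermatogenesis genes in fathers, 2 rose and 2 fell, both over all genes and adjusted over the list alone (list test adjusted p = 0.897). The 4 included the major sperm protein gene *msp-152* (1.78, one of a family of near-identical copies), *spe-44* (-0.43), which activates sperm genes, and *fer-1* (-0.47), which acts in membrane fusion of sperm. Germline core genes were shifted down (median -0.11, adjusted p = 0.0138, and adjusted p = 0.874 with an estimated correlation), with 1 of 52 called, the Argonaute gene *csr-1* (-0.43 ± 0.08). The chaperonin gene *hsp-60* fell by 0.47 and was the 1 called of 9 heat shock genes (list median 0.10 and direction of the test downward, adjusted p = 0.748). None of 31 oogenesis, 16 histone, 16 synMuv and 4 PRC2 and MES-4 genes was called by edgeR, over all genes or adjusted over the list alone (list tests adjusted p = 0.189, 0.352, 0.23 and 0.459). X-linked genes, which are low in the male germline, had a median of 1.2 over 237 genes with 2 called higher and 1 lower (0 and 1 adjusted over the list alone, adjusted p = 0.0458, and adjusted p = 0.89 with an estimated correlation). Pharynx and demethylase genes were not tested in fathers for want of counts. Leaving out 1 library gave 210 calls without *mes-3* replicate 2 (7 lower), 294 and 477 without *him-8* replicates 2 and 1 (11 and 36 lower), 452 and 476 without *mes-3* replicates 1 and 3 (75 and 51 lower), and 671 without *him-8* replicate 3 (143 lower).

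In first-cross hermaphrodite germlines, genes of muscle, intestine and neurons were among those higher in M+P- than in M+P+ worms (n = 2 per group), and X-linked genes made up most of those lower. *ketn-1*, which encodes the muscle protein kettin, averaged 480 ± 81.4 CPM against 8.502 ± 10.7 (log2 fold change 5.86 ± 0.45 SE, adjusted p = 8.14e-06). *unc-31* averaged 10.4 ± 1.41 CPM against 1.43 ± 0.0846 (2.86 ± 0.32, adjusted p = 0.000117). The X-linked *meg-1*, which acts in germ granules, averaged 99.1 ± 5.47 CPM against 204 ± 28.5 (-1.04 ± 0.09, adjusted p = 2.23e-05), and *jmjd-3.1*, an H3K27 demethylase gene on the X, 1.35 ± 0.271 against 6.09 ± 0.416 (-2.17 ± 0.35, adjusted p = 0.00154). Of 8409 genes tested, 430 rose and 389 fell in M+P- (edgeR). DESeq2 called 534, with 255 higher and 279 lower. Of the falls, 311 lay among 820 X-linked genes, of which 5 rose, while 422 autosomal genes rose and 75 fell.

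Other large rises in these germlines were *qui-1* (6.32 ± 0.49, adjusted p = 8.58e-06), the chemoreceptor-like *srm-1* (6.10), *suro-1* (5.70), *oac-36* (5.58), *oac-52* (5.57) and *cutl-17* (5.55), and *plc-2*, a phospholipase C gene, averaged 3.33 ± 0.0914 CPM against no counts. The largest falls were *rgs-6* (-4.01 ± 0.75), *lido-6* (-3.74), *zig-9* (-3.24), *set-6* (-3.15), *attf-5* (-3.03), *lido-3* (-3.005), *fbxa-125* (-2.65) and *frm-3* (-2.54). All 8 but *zig-9* and *fbxa-125* are X-linked. *mes-3* was not called (92.7 ± 3.57 against 96.5 ± 7.66 CPM, -0.06 ± 0.08, adjusted p = 0.846), nor were *mes-2* (0.03), *mes-4* (0.12), *mes-6* (-0.02), *him-8* (-0.15), *fem-2* (-0.14) and *glh-1* (0.03).

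Of 13 intestinal genes 9 rose (13 adjusted over the list alone), with a median of 1.68 (adjusted p = 1.11e-07, and adjusted p = 0.523 with an estimated correlation). They included the gut esterase gene *ges-1* (3.47 ± 0.66) and the yolk protein genes *vit-6* (50.4 ± 36.6 against 12.4 ± 3.71 CPM) and *vit-2* (1.70). Among 18 neuronal genes 5 rose and 2 fell (the same counts adjusted over the list alone, list test adjusted p = 0.182), with *egl-3* at 3.45 and the X-linked *unc-18*, which acts in vesicle fusion, at -1.46. Of 17 muscle genes, *ttn-1* (2.57) and *unc-89* (2.1) rose and the X-linked *act-4* (-0.79) fell (2 and 1 adjusted over the list alone, adjusted p = 0.0541). Cuticle genes were shifted up (median 0.40, adjusted p = 0.00807, and adjusted p = 0.568 with an estimated correlation), with *col-109* (3.36) and *col-2* (3.08) called of 38 (2 adjusted over the list alone). Oogenesis genes were shifted down (median -0.14, adjusted p = 0.000243, and adjusted p = 0.523 with an estimated correlation). The 3 called of 33 (2 adjusted over the list alone) were *meg-1* and the eggshell proteoglycan genes *cpg-2* (-0.42) and *cpg-3* (-0.39).

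Called members of the remaining lists were *fog-3* (1.75) and *fog-1* (0.44), which specify sperm fate, of 12 spermatogenesis genes, *lim-7* (1.71) of 24 homeodomain and of 11 somatic gonad genes, the X-linked *lin-15A* (-1.01) and *lin-15B* (-0.73) of 18 synMuv genes, *jmjd-3.1* of 3 demethylase genes and *ajm-1* (-1.05) of 3 pharynx genes. Adjusted over the list alone, the counts were the same except 2 for the somatic gonad. These list tests gave adjusted p = 0.228, 0.272, 0.272, 0.211, 0.17 and 0.272. None was called by edgeR of 5 neuropeptide genes (1 adjusted over the list alone) and of 53 germline core, 5 heat shock, 22 histone and 4 PRC2 and MES-4 genes (0 adjusted over each list alone), with adjusted p = 0.568, 0.691, 0.624, 0.712 and 0.865. X-linked genes had a median of -0.71, with 749 of 820 below 0 (11 higher and 450 lower adjusted over the list alone, adjusted p = 6.17e-55, and adjusted p = 0.523 with an estimated correlation). The autosomal list stood above other genes with an estimated correlation too (adjusted p = 5.24e-43 and 0.0153). Those other genes are mostly X-linked, so this mirrors the X-linked shift and is no separate result. Without M+P+ replicate 1 the calls numbered 369, of which 106 were X-linked falls, without M+P+ replicate 2 465 (232) and without M+P- replicate 1 447 (177), and a fit together with the male germlines called 23.

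In first-cross male germlines, 45 autosomal genes rose in M+P- and none fell (n = 4 per group, 9189 genes, 449 at an unadjusted p under 0.05). DESeq2 called 168, 145 higher and 23 lower. The F-box gene *fbxa-65* averaged 14.1 ± 2.29 CPM against 0.0990 ± 0.0979 (6.99 ± 0.64, adjusted p = 0.00783) and the autophagy gene *atg-16.2* 28.0 ± 1.5 against 1.39 ± 0.518 (4.33 ± 0.32, adjusted p = 0.00745). The other named rises were the chemoreceptor genes *sre-9* (6.89) and *srm-1* (6.19), *nhr-81* (6.21), the glutamate receptor gene *glr-5* (6.02), the channel gene *lgc-10* (4.79) and *clec-204* (4.66). *mes-3* (43.3 ± 2.55 against 41.6 ± 1.83 CPM), *mes-2*, *mes-6*, *mes-4*, *him-8* and *fem-2* had adjusted p = 1, and *glh-1* (0.19 ± 0.05) had adjusted p = 0.309.

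No member of any list but the autosomal one was called in male germlines by edgeR, and 1 each of the homeodomain, cuticle and somatic gonad lists was adjusted over the list alone. Oogenesis genes (median -0.25 over 30) and histone genes (median -0.24 over 20) were shifted down, each at adjusted p = 0.00798, and adjusted p = 0.923 and 0.423 with an estimated correlation. M+P+ replicate 3 stood apart. Its mean log2 CPM of muscle genes was 6.23 against 0.46 to 1.29 in the other M+P+ libraries, of somatic gonad genes 4.76 against 2.29 to 2.50, and of X-linked genes 2.52 against -1.12 to -0.96. With all 8 libraries the muscle list had a median of -1.66 while its test pointed up (adjusted p = 0.826), as did those of neuronal (-0.53), cuticle (-0.53), intestinal (-0.35), neuropeptide (-0.13), homeodomain (-0.07) and somatic gonad genes, whose medians lay below 0. X-linked genes had a median of -0.88. Without that library, an alternative singled out after seeing the data, 172 genes rose and 3 fell, the medians of muscle and X-linked genes were 2.52 and 1.36, and neuronal genes had 3 of 19 called (6 adjusted over the list alone, median 1.03). Without M+P+ replicates 1, 2 and 4 the calls numbered 21, 9 and 5, and without M+P- replicates 1, 2, 3 and 4 they numbered 26, 10, 3 and 4.

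In L1 larvae, which are mostly soma, 1 gene was called of 14618 (n = 3 per group, 1016 at an unadjusted p under 0.05). *ptr-22*, a patched-related gene, averaged 1.54 ± 0.603 CPM in M+P- and 23.7 ± 8.39 in M+P+ larvae (-3.95 ± 0.40, adjusted p = 0.0168). DESeq2 called 81 genes, 46 higher and 35 lower, and edgeR without the filter on low counts 124. No member of any list but the autosomal one was called (edgeR), and 2 muscle genes were lower adjusted over the list alone. Cuticle genes (101, median -0.25, adjusted p = 0.000578), muscle genes (23, median -0.12, adjusted p = 0.0162) and histone genes (20, median -0.45, adjusted p = 0.0319) were shifted down, and adjusted p = 0.191, 0.437 and 0.46 with an estimated correlation. Without M+P+ replicate 2 or M+P- replicate 2 the calls numbered 0, and without M+P+ replicate 1 and M+P- replicate 3 they numbered 3 and 4. *mes-3* averaged 39.1 ± 8.07 against 32.9 ± 5.16 CPM (adjusted p = 0.892).

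A test of the M+P- effect between tissues of the first cross called 0 genes between male and hermaphrodite germlines (edgeR, 17100 genes, 13 higher and 9 lower by DESeq2), 8 between larvae and hermaphrodite germlines and 23 between larvae and male germlines. The effect in larvae lay below that in male germlines for *atg-16.2* (-4.34 ± 0.51, adjusted p = 0.00404), *fbxa-65* (-5.66), *glr-5* (-5.97), *lgc-10* (-4.35) and the guanylyl cyclase gene *gcy-23* (-2.72), and above it for the Argonaute gene *alg-3* (6.30). Against hermaphrodite germlines it lay below for *kvs-2* (-7.38) and *gcy-23* (-3.69) and above for *alg-3* (6.29). *kvs-2*, *gcy-23* and *alg-3* are named after their values were seen. Without male M+P+ replicate 3 the male effect was higher than the hermaphrodite one at 41 genes and lower at 2. That for larvae was then higher at 7 and lower at 52 against hermaphrodite germlines, and higher at 25 and lower at 397 against male germlines. Without hermaphrodite M+P- replicate 1 or 2, larvae differed from hermaphrodite germlines at 1 higher and 1 lower gene, and without M+P+ replicates 1 and 2 at 1 and 2 higher genes. Genes called in at least 1 contrast numbered 26 with all libraries and 12, 11, 12 and 15 without male M+P- replicates 1 to 4. They numbered 17 and 15 without male M+P+ replicates 1 and 4, 45, 42 and 65 without larval M+P- replicates 1 to 3, and 45, 62 and 47 without larval M+P+ replicates 1 to 3.

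In second-cross F1 germlines, no gene was called between M+P- and M+P+ with all 6 libraries (edgeR, 7983 genes, 294 at an unadjusted p under 0.05), while DESeq2 called 132, 98 higher and 34 lower. M+P- replicate 3 (6925316 counts) had no counts over part of the chromosomes. Of 4957 genes with a mean above 200 counts in the other libraries, 640 had 0 counts in it, against at most 10 in any other library. All 117 such X-linked genes were at 0. On chromosome V the first 202 genes in order had counts and the remaining 519 had none. Chromosome IV genes had counts at a median log2 ratio of -2.72 to the other libraries. On chromosomes I and II alone, all 6 libraries gave 91 calls, 62 higher and 29 lower, an alternative chosen after seeing those counts.

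**Figure D1:**
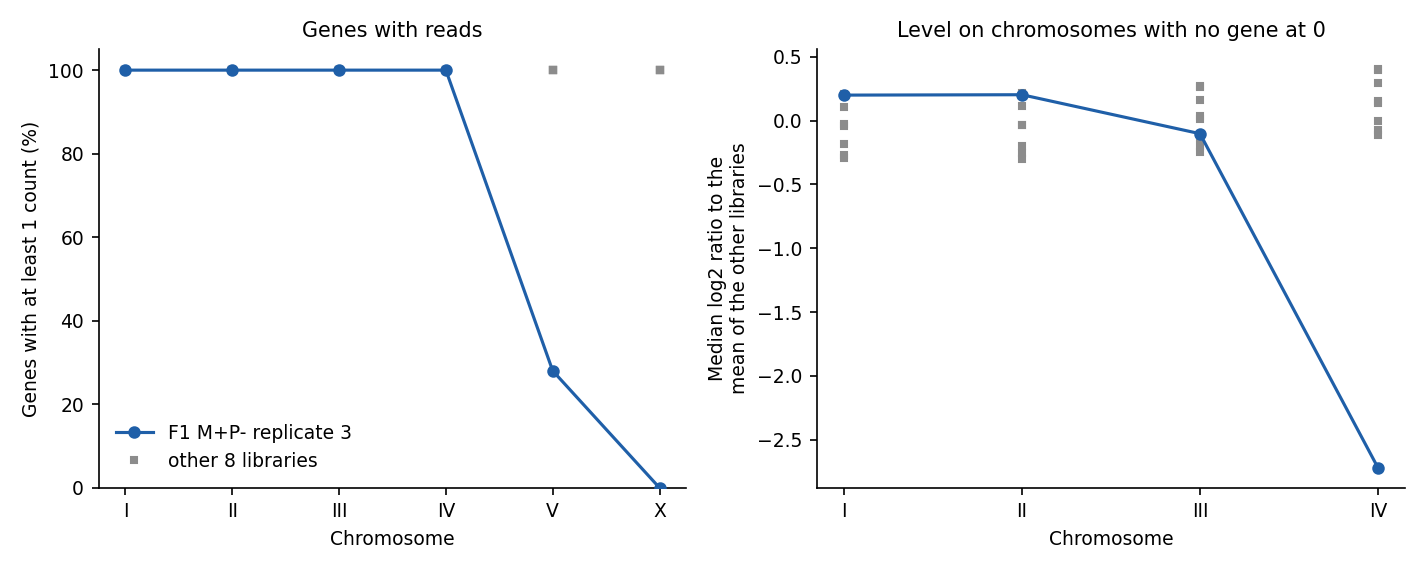
Left, percent of reference genes (mean above 200 counts in the other libraries) with at least 1 count, per chromosome and library of the second cross; right, the median log2 ratio of raw counts to the mean of the other libraries on chromosomes I to IV. F1 M+P- replicate 3 has counts for 0 of 117 genes on the X and 202 of 721 on V, and a median ratio of -2.72 on IV.

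Leaving out each library in turn was set beforehand, and the fit without M+P- replicate 3, singled out after seeing its counts, called 263 genes of 8326, 182 higher and 81 lower (n = 2 M+P- and 3 M+P+). Genes of muscle and neurons were among the rises: *ketn-1* averaged 54.9 ± 7.07 CPM against 1.10 ± 0.326 (5.64 ± 0.21, adjusted p = 5.01e-06) and *unc-31* 11.7 ± 0.582 against 2.13 ± 0.0161 (2.45 ± 0.25, adjusted p = 0.00144). Further rises were *clec-204* (7.24 ± 0.56), *lim-8* (6.38), *ule-3* (5.86), the tyrosinase gene *tyr-6* (5.76), *oac-36* (5.48), *qui-1* (5.12), *ida-1* (3.81), *ttn-1* (2.71), *ges-1* (2.69) and the synaptic gene *unc-13* (2.54), and *talp-3* averaged 5.50 ± 0.111 CPM against no counts. Falls were *dyf-2* (-2.28), *lido-5* (-2.08), *mkk-4* (-2.02), *lido-4* (-1.94), *jmjd-3.1* (-1.94 ± 0.38), *ttyh-1* (-1.79), *asna-2* (-1.78), *ccd-5* (-1.65) and *meg-1* (-0.73 ± 0.10), each but *dyf-2* on the X.

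In that fit, 55 of 823 X-linked genes fell and 5 rose (179 and 25 adjusted over the list alone, median -0.39, adjusted p = 3.28e-19, and adjusted p = 0.439 with an estimated correlation). Intestinal genes had a median of 1.43 with 1 of 17 called (13 adjusted over the list alone, adjusted p = 6.11e-11, and adjusted p = 0.439 with an estimated correlation). Muscle genes had 1 of 19 called (6 adjusted over the list alone, median 0.88, adjusted p = 7.22e-06, and adjusted p = 0.439 with an estimated correlation) and neuronal genes 3 of 19 (3 higher and 2 lower adjusted over the list alone, adjusted p = 0.112). Cuticle genes were shifted up with 0 of 46 called (edgeR, 0 adjusted over the list alone, median 0.96, adjusted p = 6.44e-09, and adjusted p = 0.458 with an estimated correlation). *mes-3* averaged 92.3 ± 5.31 against 91.6 ± 3.45 CPM (adjusted p = 0.985) there, and with all 6 libraries 105.1 ± 14.9 against 95.8 ± 3.75 (adjusted p = 0.917).

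In F2 germlines that descended from M+P- worms, genes of neurons were among those higher than in F1 M+P+ germlines (n = 3 per group). *unc-31* averaged 13.2 ± 2.75 CPM against 2.15 ± 0.0235 (2.61 ± 0.23, adjusted p = 0.00015), *tyr-6* 16.35 ± 3.23 against 0.319 ± 0.369 (5.64 ± 0.43, adjusted p = 7.97e-05) and *qui-1* 15.6 ± 0.548 against 0.338 ± 0.415 (5.55 ± 0.46, adjusted p = 0.000117). Of 8296 genes, 211 rose and 55 fell (edgeR). DESeq2 called 337. With the replicate block 393 rose and 241 fell. The largest other rises were *lim-8* (6.21), *clec-204* (5.74), *oac-36* (5.26), *sym-2* (4.83), the carbonic anhydrase-related *cah-2* (4.65) and *ida-1* (4.60). The falls named by the rule were the aldolase gene *aldo-1* (-1.49 ± 0.23), *sto-4* (-1.41), *mboa-3* (-1.31), *madf-9* (-1.15), *glna-1* (-1.15), *atrn-1* (-1.12), *chd-3* (-1.09) and *vem-1* (-1.08). *mes-3* was not called (99.1 ± 6.74 against 92.2 ± 3.87 CPM, adjusted p = 0.551), nor were *mes-2*, *mes-4*, *mes-6*, *him-8*, *fem-2* and *glh-1*, whose log2 fold changes ran from -0.18 to 0.04.

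Of 20 neuronal genes 5 rose in F2 (7 higher and 1 lower adjusted over the list alone, adjusted p = 5.87e-05, and adjusted p = 0.127 with an estimated correlation), among them *unc-13* (2.53) and *egl-3* (2.27). *ttn-1* (2.65) was the 1 called of 19 muscle genes (3 adjusted over the list alone, median 0.63, adjusted p = 6.12e-05, and adjusted p = 0.704 with an estimated correlation) and *ges-1* (2.35) the 1 of 16 intestinal genes (1 adjusted over the list alone, median 0.51, adjusted p = 0.00421, and adjusted p = 0.762 with an estimated correlation). Cuticle genes were shifted up with 0 of 42 called (edgeR, adjusted p = 0.000479) and oogenesis genes down with 0 of 33 called (edgeR, adjusted p = 0.0138), and adjusted p = 0.704 for both with an estimated correlation. *lim-7* (1.46) was the 1 called of the homeodomain and of the somatic gonad lists. Of 812 X-linked genes 32 fell and 0 rose (81 lower and 2 higher adjusted over the list alone, median -0.38, adjusted p = 4.9e-19, and adjusted p = 0.704 with an estimated correlation). With the replicate block, 21 of 42 cuticle, 8 of 19 muscle, 6 of 16 intestinal and 6 of 20 neuronal genes rose, and 151 X-linked genes fell and 20 rose. The autosomal list stood above other genes, which are mostly X-linked, with an estimated correlation (adjusted p = 0.00489), and with the replicate block too this became adjusted p = 0.0732. It mirrors the X-linked shift. Without M+P+ replicate 1 the calls numbered 141 (10 lower), without GM+GP- replicate 1 155 (15 lower) and without GM+GP- replicate 3 125 (9 lower). The X-linked falls were then 6, 7 and 6. Without M+P+ replicates 2 and 3, 34 and 36 genes fell (15 and 21 X-linked), without GM+GP- replicate 2 78 fell (65 X-linked), and a fit together with the F1 M+P- libraries called 1.

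F2 germlines set against F1 M+P- germlines gave 0 calls with all 6 libraries (edgeR, 8229 genes, 54 at an unadjusted p under 0.05, 3 by DESeq2) and 4 without F1 M+P- replicate 3 (21 by DESeq2). *unc-73* was higher in F2 (0.56 ± 0.08, adjusted p = 0.0484). *aldo-1* (7.747 ± 1.2 against 62.01 ± 28.7 CPM, -3.004 ± 0.26, adjusted p = 0.00351), the lactate dehydrogenase gene *ldh-1* (-0.88 ± 0.09) and *ketn-1* (10.3 ± 4.42 against 55.2 ± 7.62 CPM, -2.43 ± 0.28, adjusted p = 0.0148) were lower. In that fit intestinal genes had a median of -0.87 with 0 called by edgeR (7 lower adjusted over the list alone, adjusted p = 1.02e-17, and adjusted p = 0.424 with an estimated correlation).

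The genes called in the first and second crosses were set side by side. With all F1 libraries the crosses shared 0 calls, since F1 had none by edgeR (69 shared among DESeq2 calls, and 2 at an adjusted p under 0.1). Without F1 M+P- replicate 3, 139 genes were higher in both crosses against 7.08 for independent lists (Fisher's exact test, p = 3.54e-177), and 61 were lower in both against 3.7 (p = 1.29e-66). *oac-36*, *qui-1* and *ketn-1* were higher in hermaphrodite germlines of both crosses. F1 and F2 shared 0 calls with all libraries (84 by DESeq2), and without replicate 3 127 higher and 31 lower, against 3.6 and 0.548 for independent lists. These 2 comparisons used the same M+P+ libraries. In 40 simulations of unchanged groups against such controls, the mean number shared was 0.025 higher and 0.05 lower. Those groups held no changed genes, so the simulations cannot show how many calls shared controls add where genes do change. The covariance of the log2 fold changes of the 2 comparisons across genes was 0.314 against 0.0256 in the simulations. Their correlation was 0.895 against 0.453. The 3 controls were too few to split, so part of the excess may come from sharing them.

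Genes called higher in mutant fathers and in offspring were also compared, which share no libraries. Somatic RNA in the samples of fathers was not tested as a source of shared calls. Fathers and first-cross hermaphrodite germlines shared 172 higher genes against 23.6 for independent lists (Fisher's exact test, p = 1.82e-117), and fathers and male offspring 30 against 2.29 (p = 8.55e-31). *oac-36*, *col-109*, *egl-3*, *unc-31*, *lim-7*, *ttn-1* and *unc-89* were among the genes called higher in both fathers and hermaphrodite offspring, and *nhr-81* in fathers and male offspring. Fathers and hermaphrodite offspring shared 2 lower genes, *arrd-13* and *wdfy-3*, against 1.95, and 19 genes were higher in fathers and lower in the offspring. All 43 genes higher in male germlines and tested in both sexes were higher in hermaphrodite germlines. Of the genes higher in first-cross hermaphrodite germlines, 94.1% of 358 were above 0 in second-cross F1 without replicate 3 (median 1.49), 89.7% of 360 in F2 (median 1.30), 93.3% of 329 in fathers (median 2.66), 83.6% of 366 in male germlines (median 0.96) and 52.7% of 387 in larvae (median 0.03). Without male M+P+ replicate 3 the male values were 94.7% of 379 and a median of 2.23. The genes lower in hermaphrodite germlines were also above 0 in fathers, at 88.2% of 119 (median 1.2). In the other comparisons 5.88% of 136 were above 0 in male germlines (50% of 138 without M+P+ replicate 3), 5.15% of 369 in second-cross F1 without replicate 3, 5.63% of 373 in F2 and 27.8% of 342 in larvae.

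Reads were then assigned to the parental alleles. At the genes called higher in first-cross hermaphrodite germlines, 81.3% ± 1.99 of allele-assigned reads were paternal in M+P- against 57.6% ± 2.79 in M+P+ (SD, n = 2 per group, exact p = 0.333, the smallest possible). These genes were chosen on the summed counts of the same samples. Male germlines are separate samples, and at the same genes they had 68.3% ± 1.73 against 52.7% ± 0.58 (n = 4 per group, exact two-sided p = 0.0286). At the genes higher in male germlines the shares were 87.8% ± 3.49 and 54.8% ± 10.9 (exact p = 0.0286). These 45 genes were chosen on the summed counts of the same male libraries, so this is no separate test, and 19 of them had allele reads. The differences without M+P- replicate 2 or 3, 31.9 and 32.4 points, were no longer past the threshold. Over all genes the shares were 53.1% against 52.0% in hermaphrodite germlines (exact p = 0.333) and 53.0% against 52.0% in male germlines, a difference of 1.09 points (exact p = 0.0286). On the X alone male germlines had 3.00% against 6.46% (exact p = 0.0286). Males get their X from the mother, so these reads check the allele assignment and show no change of a paternal X. M+P+ replicate 2 was the highest, at 11.85%. Hermaphrodite germlines had 52.5% against 48.1% on the X (exact p = 0.333) and larvae 33.9% against 37.4% (exact p = 0.3). In larvae the share at the genes higher in hermaphrodite germlines was 53.9% against 50.1% (n = 3 per group, exact p = 0.1, the smallest possible).

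In the second cross, the paternal share at the genes higher without replicate 3 was 82.5% ± 1.35 in F1 M+P- (n = 2) against 64.2% ± 2.65 in M+P+ (n = 3, exact p = 0.1), and at the genes higher in F2 it was 78.7% ± 2.47 in F2 against 57.3% ± 0.81 (n = 3 per group, exact p = 0.1, the smallest possible). Each of these sets was chosen on the summed counts of the same samples. F2 shares per chromosome ran from 44.42% to 57.01%, against 49.01% to 53.65% in F1 M+P+. At the first-cross set, chosen on other samples, the shares were 77.7% in F1 M+P- and 74.5% in F2 against 64.3% in M+P+. Over all genes they were 52.6% in F1 M+P- and 52.4% in F2 against 51.8% in M+P+.

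**Figure D2:**
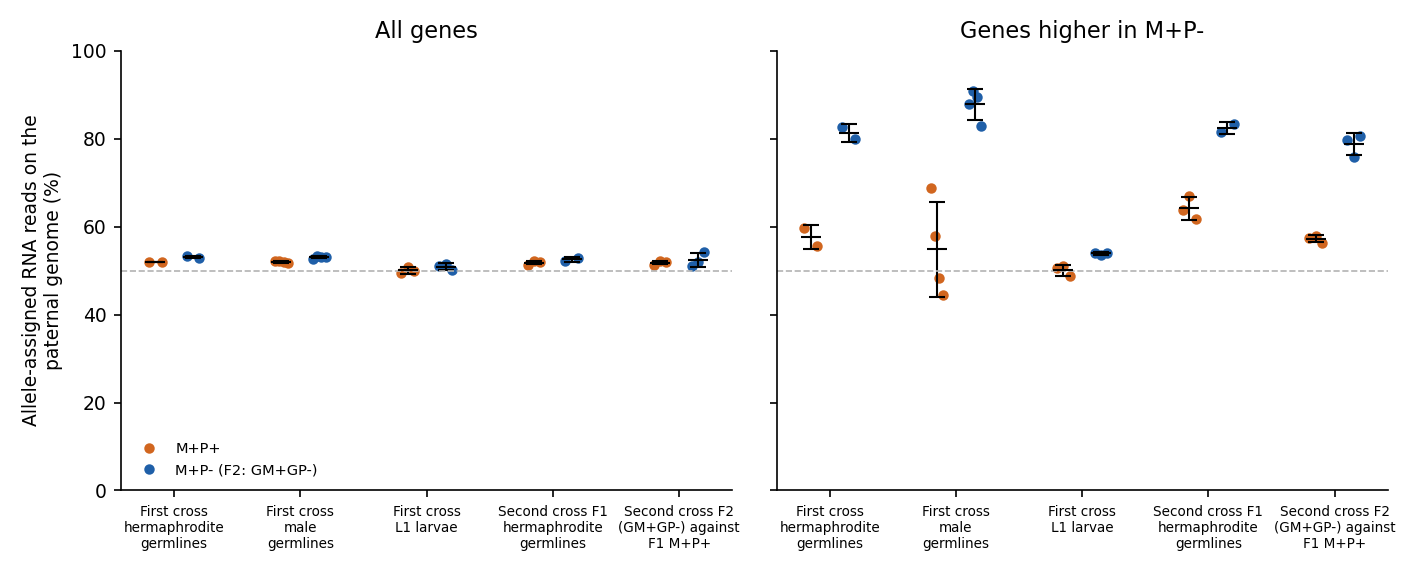
Percent of allele-assigned RNA reads on the paternal genome, over all genes (left) and over genes called higher (right), for M+P- or GM+GP- and M+P+ groups. Points are libraries, bars the mean ± SD, and the dashed line 50%. The set is that of hermaphrodite germlines for hermaphrodite germlines and larvae, and each group's own set elsewhere; F2 is set against F1 M+P+. At higher genes the means were 81.3% and 57.6% in hermaphrodite germlines and 53.9% and 50.1% in larvae.

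Per gene, the paternal allele rose against the maternal one in M+P- at 9 of 2209 genes in hermaphrodite germlines, 7 of 2476 in male germlines, 1 of 3427 in larvae and 1 of 2039 in F1 (edgeR). The tankyrase gene *tank-1* was 87.3% paternal in M+P- against 46.2% in M+P+ hermaphrodite germlines (log2 difference 3.00 ± 0.40, adjusted p = 1.52e-06) and 88.0% against 56.1% in male germlines (2.52 ± 0.23, adjusted p = 4.69e-10). In male germlines *ketn-1* was 92.4% against 31.9% paternal (4.70 ± 0.55, adjusted p = 5.83e-07), while its summed counts were not called there (adjusted p = 1). Of the genes called by allele, 7 of 9 in hermaphrodite germlines, 1 of 7 in male germlines and 0 in larvae and in F1 were also called higher in summed counts. *mex-6*, which acts in embryonic polarity, was 61.3% against 47.6% in first-cross hermaphrodite germlines (0.82 ± 0.18, adjusted p = 0.00718) and 58.3% against 46.0% in F1 (0.71 ± 0.14, adjusted p = 0.0465). The others in hermaphrodite germlines were T10D4.6, *lido-7*, F25E5.1, *sma-1*, *lido-9*, C50E3.13 and R03H10.6, and in male germlines F25E5.1, *lido-7*, Y25C1A.13, *nra-4* and *dnbp-1*. In larvae the gene was R03H10.6, 35.7% against 1.35% paternal (5.67 ± 0.76, adjusted p = 3.48e-10). These genes are named by their calls and were outside the rule. The hermaphrodite count was 0 without M+P+ replicate 1 or 2 and 5 without M+P- replicate 1, the male count 3 without M+P+ replicate 3 and 4 without M+P- replicate 2, and the F1 count 0 without any 1 library. The larval count was 3 without M+P+ replicate 1 and 2 without M+P+ or M+P- replicate 2.

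H3K27me3 was lower in M+P- germlines at the genes whose RNA was higher. Over 420 such genes in the first cross the mean log2 fold change of H3K27me3 was -0.28, with 388 below 0 (camera p = 3.19e-44, and p = 0.0329 with an estimated correlation). The latter became 0.0522 without M+P+ replicate 1, 0.171 without M+P- replicate 1 and 0.2 without M+P- replicate 2. Mean log2 CPM was 5.91 and 5.90 in the M+P- libraries, 6.13 and 6.20 in M+P+, and 6.14 and 6.07 in *him-8* fathers. The authors' deposited z-scores averaged 0.288 and 0.292 against 0.411 and 0.458. At *ketn-1* H3K27me3 was 310 and 335 CPM in M+P- against 479 and 478 in M+P+, and at *qui-1* 190 and 213 against 273 and 336. At the 387 genes whose RNA was lower, the mean was 0.10 (p = 1.87e-07, and p = 0.151 with an estimated correlation). In F1 the mean over 177 genes was -0.14 (p = 0.0628 with an estimated correlation) and in F2 over 206 genes -0.12 (p = 0.00928, and p = 0.405 with an estimated correlation). The F2 call was lost without M+P+ replicate 1 (-0.09) and without GM+GP- replicate 2 (-0.09).

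H3K36me3, a mark of transcribed genes, was higher at these genes, by 0.54 in the first cross (p = 0.0816 with an estimated correlation), 0.76 in F1 (p = 0.0118 with an estimated correlation) and 0.61 in F2 (p = 0.138 with an estimated correlation). The medians over all genes were -0.09, -0.01 and 0.24, so part of the F2 value was shared by all genes. The first-cross value rests on 2 M+P+ libraries, of which replicate 2 stood apart with 41980395 counts. Camera with the preset correlation gave p = 6.81e-22, 2.49e-81 and 2.75e-20. In F1 the p with an estimated correlation was 0.0596 and 0.086 without M+P+ replicates 1 and 2, and 0.101 and 0.0879 without M+P- replicates 1 and 2. In F1, *qui-1* rose to 243 and 188 CPM from 60.3 and 95.1 (1.47 ± 0.20, adjusted p = 0.00265) and *ketn-1* to 174 and 144 from 74.5 and 82.2 (1.02 ± 0.18, adjusted p = 0.0258).

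**Figure D3:**
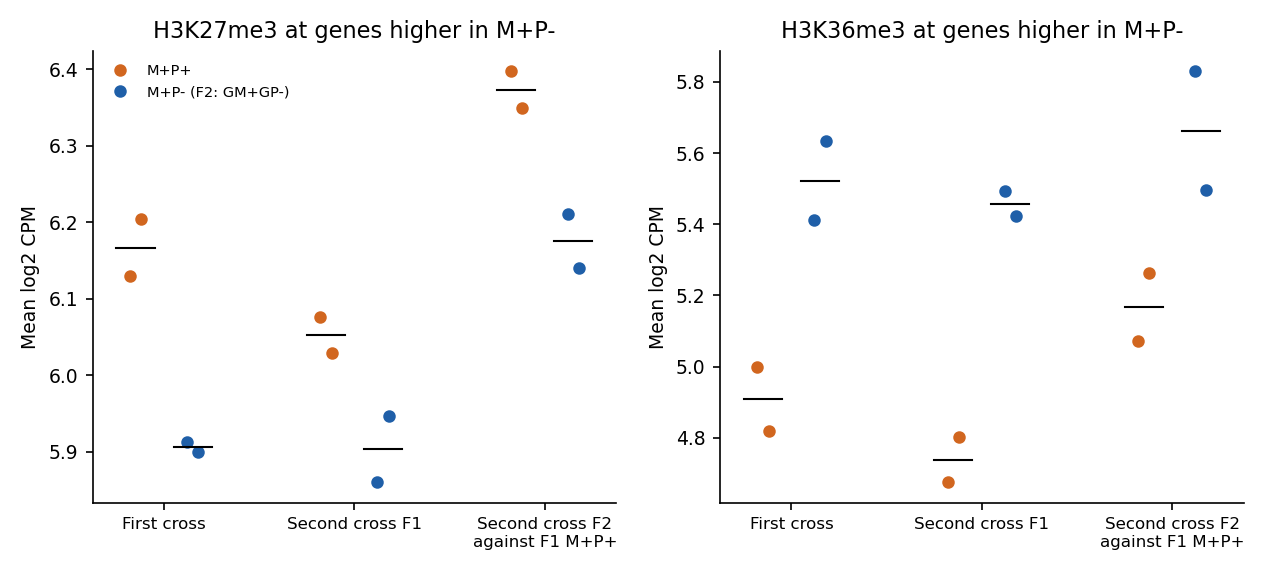
Mean log2 CPM of H3K27me3 and H3K36me3 over the genes whose RNA was called higher, per CUT&RUN library. Points are the 2 libraries of a group and the line their mean. In the first cross H3K27me3 was 5.91 and 5.90 in M+P- and 6.13 and 6.20 in M+P+.

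Gene by gene, H3K27me3 gave 0 calls in the first cross (edgeR, 29121 genes, 299 at an unadjusted p under 0.05, 0 by DESeq2) and 0 in F1 (29099 genes, 615 at an unadjusted p under 0.05, 0 by DESeq2). In F2 against F1 M+P+ germlines 189 genes rose and 2881 fell (29073 genes). No background control or spike-in entered this test, so a difference in background between libraries cannot be told apart from a change in the mark. The falls held 27 of 53 germline core genes (37 adjusted over the list alone, median -0.59, adjusted p = 3.68e-16, and adjusted p = 0.247 with an estimated correlation) and 10 of 17 synMuv genes (13 adjusted over the list alone, median -0.77, adjusted p = 9.3e-08, and adjusted p = 0.335 with an estimated correlation). Also lower were *mes-2* (19.6 and 23.1 CPM against 35.1 and 34.7, -0.71 ± 0.18, adjusted p = 0.0106), *mes-3* (-0.79 ± 0.16, adjusted p = 0.00242) and *mes-4* (-0.57 ± 0.16, adjusted p = 0.02). *unc-31* fell (-0.38 ± 0.10, adjusted p = 0.0176) and *ttn-1* rose (0.19 ± 0.06, adjusted p = 0.0333). X-linked genes gave 54 of the rises and 0 falls of 3930 tested (adjusted p = 3.68e-16, and adjusted p = 0.0968 with an estimated correlation). The X-linked rises numbered 9 without GM+GP- replicate 1, 14 without M+P+ replicate 2 and 143 without M+P+ replicate 1. All rises numbered 28 without M+P+ replicate 2 and 559 without M+P+ replicate 1. Without M+P+ replicate 2 the F2 calls numbered 1473, and the F1 calls without M+P- replicate 1 and 2 numbered 2 and 180. The first-cross calls without M+P+ replicate 1 and M+P- replicate 2 numbered 2 and 1.

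H3K36me3 gave 0 calls in the first cross (edgeR, 24469 genes, 132 at an unadjusted p under 0.05, 0 by DESeq2), 29 higher in F1 (24018 genes, 110 by DESeq2) and 0 in F2 (24592 genes, 3688 at an unadjusted p under 0.05, 0 by DESeq2). In the first cross M+P+ replicate 2 stood apart, with 41980395 counts on 22807 genes. Without M+P+ replicate 1 11392 genes were called and without M+P+ replicate 2, 71. In F1 the calls numbered 12 and 267 without M+P+ replicates 1 and 2, and 8 and 90 without M+P- replicates 1 and 2. In F2 they numbered 5715 and 9 without GM+GP- replicates 1 and 2 and 41 without M+P+ replicate 2. Scaling mattered here: the median log2 fold change of all genes was -0.09 in the first cross and 0.24 in F2, and 0.09 and 0.50 when scaled by library size only.

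On the paternal allele, H3K27me3 made up 38.6% ± 6.53 of allele-assigned reads at the genes higher in first-cross M+P- germlines against 50.6% ± 0.35 in M+P+, and H3K36me3 72.5% ± 5.44 against 58.1% ± 2.57 (SD, n = 2 per group, exact p = 0.333, the smallest possible). In F1 H3K27me3 was 43.1% ± 4.92 against 51.3% ± 0.364 and in F2 40.6% ± 4.74 against 50.6% ± 0.344, at each comparison's own genes (n = 2 per group, exact p = 0.333). The F2 libraries differed by chromosome. On chromosome IV H3K27me3 was 39.88% and 56.14% paternal in F2 replicates 1 and 2, and H3K36me3 53.32% and 66.73%. F1 M+P+ replicates 1 and 2 had 55.26% and 50.35% for H3K27me3 there. F2 shares at the called genes were not adjusted for such differences. Over autosomes the H3K27me3 shares were 46.4% against 52.6% in the first cross, 47.1% against 51.4% in F1 and 49.4% against 51.4% in F2. Those of H3K36me3 were 58.0% against 54.7% in the first cross, 58.0% against 54.9% in F1 and 55.3% against 54.9% in F2. Tested per gene on 1 allele at a time, paternal H3K27me3 gave 3 lower genes in the first cross and 2 in F2 (edgeR), and 0 in F1 (430 at an unadjusted p under 0.05). Maternal H3K27me3 gave 0 in each (91, 338 and 928 at an unadjusted p under 0.05 in the first cross, F1 and F2). H3K36me3 gave 0 on either allele (123, 322 and 636 paternal and 66, 115 and 513 maternal genes at an unadjusted p under 0.05). Allele tests by other tools were not run.

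The authors' deposited table lists 327 higher and 295 lower genes in first-cross hermaphrodite germlines, of which 301 and 276 were called here too. For male germlines the authors' deposited table gives 168 and 22 (43 and 0 shared), for larvae 43 and 35 (0 and 1 shared) and for fathers 825 and 408 (517 and 104 shared). For F1 the authors' deposited table lists 275 higher and 134 lower genes. Of these, 166 and 70 were shared with the fit without M+P- replicate 3, whose log2 fold changes correlated across genes with the authors' at 0.973, against 0.851 for the fit with all 6 libraries. For F2 the authors' deposited table has 251 and 74 (197 and 44 shared).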

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

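In first-cross male germlines, M+P+ replicate 3 held more RNA of somatic and X-linked genes than the other M+P+ libraries (n = 4 in the group). Its mean log2 CPM was 2.90 for neuronal genes (others -0.34 to -0.16), 2.18 for neuropeptide genes (-1.40 to -1.22), 2.90 for homeodomain genes (1.57 to 1.73) and 6.23 for muscle genes (0.46 to 1.29). For somatic gonad genes it was 4.76 (2.29 to 2.50), for X-linked genes 2.52 (-1.12 to -0.96) and for autosomal genes 4.54 (3.801 to 3.827). *nhr-81* was at 0.0868 CPM in this library and at 0 in the other M+P+ libraries, and *sre-9* at 0.156 CPM in M+P+ replicate 2 and at 0 elsewhere in the group. Genes with reads numbered 16328 in M+P+ replicate 3, 12812 to 13713 in the other M+P+ libraries and 13340 to 15676 in the M+P- libraries.

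The effect of M+P- differed between larvae and hermaphrodite germlines at 8 genes and between larvae and male germlines at 23, with *alg-3* above and *gcy-23* below in both. When the libraries of the larvae and male germlines were regrouped, 17 of 100 groupings gave at least 23 genes. The highest other counts, 1549, 1529 and 1467, came from groupings that put male M+P- replicates 1 to 3 with M+P+ replicate 3. That points to a structure of the male samples, and chance is not excluded for the 23 genes. In F2 germlines the paternal share of chromosome III was 57.0% in replicate 3 and 44.4% in replicate 1. Of 18 F2 values per chromosome and library, 9 lay outside the range of F1 M+P+ libraries, 49.01% to 53.65%.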

How the results depend on the processing

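Of the results that answer a comparison, 195 values stayed the same under an alternative, 68 moved, 29 were stronger and 19 weaker. Outside these, medians in male germlines changed sign without M+P+ replicate 3, from -1.66 to 2.52 for muscle and from -0.88 to 1.36 for X-linked genes. For named genes and single values, 2112 stayed the same, 345 were weaker, 15 moved and 4 were stronger. The cause of each difference was not tested.

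For fathers, no filter on low counts gave 1281 calls, the replicate block 2026 and leaving out 1 library 210 to 671. For first-cross hermaphrodite germlines, DESeq2 gave 534, the fit with all germline libraries together 23 and leaving out 1 library 369 to 748. For male germlines, no filter gave 24, DESeq2 168, the replicate block 11, all germlines together 68 and leaving out 1 library 3 to 175. For larvae, no filter gave 124, DESeq2 81, the replicate block 7 and leaving out 1 library 0 to 4. The tissue test gave 45 with RLE, 55 with a mean CPM of at least 1, 455 with DESeq2, 0 with the replicate block and 11 to 443 without 1 library.

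For second-cross F1, DESeq2 gave 132, all germlines together 4, chromosomes I and II alone 91, DESeq2 without M+P- replicate 3 320 and leaving out 1 library 0 to 263. For F2, no filter gave 814, the replicate block 634, all germlines together 1 and leaving out 1 library 125 to 304. For F2 against F1 M+P-, DESeq2 gave 3, chromosomes I and II alone 3, DESeq2 without M+P- replicate 3 21 and leaving out 1 library 0 to 4. The overlap of the crosses held 2 genes at an adjusted p under 0.1, 69 with DESeq2 and 200 without M+P- replicate 3. The overlap of F1 and F2 held 2, 84 and 158.

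For H3K27me3, the replicate block gave 2988 calls in the first cross, 704 higher and 2284 lower, and 6 in F1. Leaving out 1 library gave 0 to 2, 0 to 180 and 1473 to 3471 in the first cross, F1 and F2. For H3K36me3 in the first cross the replicate block gave 7 and leaving out 1 library 0 to 11392. In F1 no filter gave 108, DESeq2 110, the replicate block 1137 and leaving out 1 library 8 to 267. In F2 scaling by library size only gave 18, the replicate block 1433 and leaving out 1 library 0 to 5715. Among named genes the replicate block called *mes-3* in fathers (adjusted p = 0.0486) and lost *cpg-2* in hermaphrodite germlines (0.0824) and *sre-9*, *nhr-81*, *srm-1*, *glr-5*, *lgc-10* and *clec-204* in male germlines (adjusted p up to 0.0942). In the comparison of F2 with F1 M+P+, whose numbers pair, the replicate block (634 calls) ended the call of the autosomal list with an estimated correlation and changed no other call of a list or named gene. Blocked list tests were run for that comparison alone. Elsewhere libraries correlated best with their own number in 2 of 3 pairs for fathers, larvae and F1, 1 of 4 for male germlines and 3 of 3 for F2 against F1 M+P-. With 2 pairs the correlations were 0.707 for H3K27me3 and 0.465 for H3K36me3 in the first cross, 0.221 for hermaphrodite RNA, 0.227 and 0.251 for H3K27me3 and H3K36me3 in F1, and -0.0542 and 0.286 in F2. At higher genes the estimated correlation gave p = 0.0816 for H3K36me3 in the first cross, 0.0628 for H3K27me3 in F1, and 0.405 and 0.138 for H3K27me3 and H3K36me3 in F2. The mean for H3K27me3 in F2 ran from -0.0936 to -0.166 without 1 library. Of 79 gene list calls, 2 remained with an estimated correlation.

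Paternal allele calls in F1 numbered 3 with at least 30 reads, 4 with at least 5, 0 with each allele scaled by its own total and 0 to 0 without 1 library. Without 1 library they were 1 to 3 in larvae, 0 to 10 in hermaphrodite and 3 to 9 in male germlines. The paternal share difference at the genes higher in male germlines, 33 points, was 31.9 and 32.4 without M+P- replicates 2 and 3 and 37.6 without M+P+ replicate 1.

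Named genes kept their call in 316 of the values and lost it in 69 for fathers, 283 and 83 for hermaphrodite germlines, 65 and 47 for male germlines, 9 and 2 for larvae and 203 and 61 for F2. For fathers and larvae the fit together holds the same libraries as the comparison itself.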

Other observations

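All tests weighed below were chosen after the results were seen.

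In first-cross M+P- germlines H3K27me3 was lower on average at genes chosen on other samples too. These sets are no separate test, since 43 male and 172 fathers' genes were shared with the hermaphrodite set. The H3K27me3 libraries were also the same. At 43 genes higher in male germlines the mean log2 fold change was -0.44 (p = 0.0112 with an estimated correlation), and at 607 genes higher in fathers it was -0.16 (p = 0.00255). For the 43 genes p with an estimated correlation was 0.068 and 0.0585 without M+P+ replicates 1 and 2, and 0.0534 and 0.0805 without M+P- replicates 1 and 2. For the 607 genes it was 0.0513, 0.0642 and 0.0521 without M+P+ replicates 1 and 2 and M+P- replicate 2.

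Genes rose in M+P- germlines, with a higher paternal share over the pooled reads of the set. In male germlines the excess at the hermaphrodite set was 15.6 points, against 3.83 in larvae, which are mostly soma. Of the 430 genes of the set, 200 had allele reads in male germlines. The excess argues against somatic RNA with the shares of larvae as its only source. Somatic marker genes were 66.5% and 67.6% paternal in M+P- and M+P+ male germlines, against 45.7% and 47.4% in larvae. Larvae may therefore not stand for the somatic RNA of these samples, and somatic RNA is not excluded. A paternal shift as large as 15.6 points over the pooled reads of all genes is excluded by the 1.09 points seen in male germlines. A smaller broad change is not excluded. In male germlines the shares over all genes were 52.67% to 53.28% in M+P- and 51.7% to 52.11% in M+P+. The paternal share of H3K27me3 over autosomes was 46.4% against 52.6% in the first cross (exact p = 0.333). For somatic marker lists in hermaphrodite germlines, the difference in paternal share was 0.0738 points on 343 genes (588 and 620 reads), which cannot tell the explanations apart. Loss of H3K27me3 from the sperm genome may act on these genes, which were also lower in H3K27me3, or the lower mark could follow from their transcription.

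Of 820 X-linked genes, 311 fell in M+P- hermaphrodite germlines (106 without M+P+ replicate 1 and 177 without M+P- replicate 1). Scaling is excluded, since the difference between the medians of X-linked and autosomal genes was -0.725 and ran from -0.588 to -0.858 across alternatives. A lower share of somatic RNA would lower somatic genes about as far, and the lower quartile of autosomal members was -0.174 or higher in each of 8 somatic lists, a test reworked after the lists were seen and blind to rises that mask a fall. Fewer late oocytes would lower autosomal oogenesis genes alike only if X-linked genes are used at the same stages, which was not tested. The median of the autosomal oogenesis genes was -0.142, with 24 of 31 below 0. Neither explanation is therefore excluded. The cause could also lie in the X itself.

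With all 6 libraries edgeR called no gene in F1, while DESeq2 called 132. Missing counts in M+P- replicate 3 fit, since chromosomes I and II alone gave 91 calls. Low depth is excluded by 117 of 117 X-linked genes at 0. A mislabelled sample of another tissue is excluded, as on chromosomes I and II the library's rank correlation across genes was 0.93 with first-cross hermaphrodite germlines and lower by 0.119 with the next tissue (0.116 to 0.126 in the other libraries of the cross). A swap within hermaphrodite germlines was not tested.

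Calls were also counted after regrouping the libraries, in all distinct ways except for the tissue test, where 100 were drawn. In male germlines 1 of 35 groupings, the real one, gave as many as 45 calls, and for its allele test 1 of 35 gave as many as 7 (highest other 2). In fathers (739), larvae (1) and F2 (266), 1 of 10 groupings gave as many, with a highest other count of 0, and 10 groupings cannot show a share under 0.05. In F1 and in F2 against F1 M+P-, both with 0 calls by edgeR, 10 of 10 gave as many, which a count of 0 fixes in advance. For the allele test in larvae 7 of 10 gave as many. For larvae against male germlines 17 of 100 gave as many as 23.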
